A study of Homo sapiens with 2 samples.

How the data were processed

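Single-cell 3′ libraries of 2 sorted populations of cultured human lung airway epithelial cells, EpCAM+ CCR10+ (CCR10pos) and EpCAM+ CCR10- (CCR10neg), were analysed, with 1 library per group as the labels give it. The number of donors is not given in the sources used here. Libraries were made with 10x Genomics v2 chemistry, in which UMIs count molecules, per the labels' protocols. Cell Ranger 1.3.0 and STAR 2.5.1 are named per the submitters' processing notes. These notes name the mouse build mm10, whereas all gene identifiers in the files are human Ensembl identifiers, so the human build and annotation are not given in the sources used here. How barcodes were called as cells is likewise not given.

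For each library the authors deposited a table of raw UMI counts per gene and cell and a table of normalized values. The raw tables held whole numbers for 33694 genes. The authors' normalized signal values equalled the raw counts times the library's median UMI total divided by the cell's total, as checked on every value of the deposited tables. Each library was thus scaled to its own median, 32920 and 28389 UMIs, so the normalized tables of the libraries are not on a common scale. Raw counts were used for all main results.

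Cells with at least 500 detected genes and at most 20% mitochondrially encoded UMIs were kept, which removed 0 CCR10pos and 2 CCR10neg barcodes. Counts were summed over the kept cells of a library and expressed as CPM. With 124038070 and 112854186 UMIs, a count of 0 allows up to 0.0242 and 0.0266 CPM (3 counts), and up to 0.0839% and 0.0777% of cells with a UMI. No test was run and no p-value computed, since cells are not replicates. Log2 ratios have conditional binomial (Clopper-Pearson) 95% intervals, sums exact Poisson intervals and shares exact binomial (Clopper-Pearson) intervals, all covering counting error only. A gene was counted as higher or lower by size when the ratio was at least 2 and the higher library had at least 20 CPM. Total counts set the scale. The median-of-ratios and TMM factors shifted it by 0.053 and 0.051 on the log2 scale.

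For clustering, counts were scaled to 10000 per cell and log-transformed, 2000 variable genes without mitochondrial, ribosomal and sex-linked genes were taken, and 30 principal components and 15 neighbours were used for Leiden clustering at resolution 0.5 (scanpy 1.11.5, igraph 0.11.9). A cluster was named only when at least 3 markers of a class fixed beforehand had at least 5 CPM and 2 times the level of other cells, with at least 1 marker among the 10 leading genes and no other class with more there. The markers were fixed before the data were examined, but these thresholds were set after the clusters had been seen. The condition on the 10 leading genes was added because, without it, cluster 4 met the alveolar type 1 class through 3 markers, AQP5, RTKN2 and EMP2, while 86 cycle genes were raised in it. Cluster 4 was therefore left unnamed. Cluster-standardised values are means of within-cluster CPM with the same weights in both libraries, over clusters with at least 50 cells of each library, so the mesenchymal-like cluster is not in them. Scrublet, run per library, called 10 of 7436 cells (0.134%) as doublets, which means that it has not worked here. Doublets were therefore kept.

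Gene lists used members with at least 5 CPM in either library. A list's median log2 ratio was placed among 10000 random lists drawn from 20 bins of mean expression. The 35 lists covered markers of epithelial, mesenchymal, endothelial and immune cells, the cell cycle, fibrosis, senescence, inflammation, stress, metabolism, signalling and adhesion. The named genes were the 12 highest and 12 lowest ratios among genes with at least 50 CPM, UMIs in at least 10% of cells of the higher library and the same sign in each of the 6 clusters with at least 100 cells of each library. CCR10, EPCAM and EPHA3, up to 4 members per list with at least 10 CPM and the largest absolute ratios, and 5 leading genes per cluster could be named too. Of the list members the text names only a part, chosen after the values were seen. Mitochondrial and ribosomal genes were given as lists only, and sex-linked genes and genes with common germline deletions were left out. Thinning drew each cell down to 12500 UMIs without replacement and left out shallower cells.

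On simulated counts with 200 changed genes among 5529, all 100 genes set 3-fold apart were at least 2-fold apart, and 0% of the 100 genes set 1.5-fold apart and of the 5329 unchanged genes were. Intervals held the true ratio for 95.38% of the unchanged genes, 96.0% of the 1.5-fold genes and 93.0% of the 3-fold genes. The counts were Poisson draws, the model behind the intervals, without variation between cells or libraries and without co-expression within lists. Coverage near 95% was thus built in, and these runs check the computation only. Of 400 random unchanged lists drawn on 9718 simulated genes, 4.0% fell outside the middle 95%.

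Alternatives were other scalings, equal weight per cell, thinning, other cell filters, Scrublet calls left out, other expression minimums and folds, equal cluster weights, the authors' normalized values, other clustering settings and other cycle thresholds. They were fixed before the data were examined, and leaving out clusters and the threshold of 20 UMIs were added afterwards. Ensembl identifiers were looked up in GENCODE 29 on GRCh38, where 33132 of 33694 matched. That annotation may not be the authors', and the tables themselves carry no coordinates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.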

Results

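Droplet-based single-cell RNA sequencing was used to compare 2 sorted populations of cultured airway epithelial cells from lung with idiopathic pulmonary fibrosis, a progressive scarring disease. Cells released from explanted lung were expanded in medium conditioned by senescent fibroblasts. After a short passage in an airway epithelial expansion medium, cells stained for EpCAM, an epithelial surface protein, and CCR10, a chemokine receptor, were sorted by flow cytometry. The CCR10pos library held EpCAM+ CCR10+ cells and the CCR10neg library EpCAM+ CCR10- cells. There was 1 library per group, so no difference below has a replicate check, and all intervals are 95% intervals that cover counting error only. The CCR10pos library held 3575 barcodes with 124038070 UMIs (unique molecular identifiers, counts of captured transcripts). Its median cell had 32920 UMIs and 5704 detected genes. The CCR10neg library kept 3861 of 3863 barcodes, with 112854186 UMIs and medians of 28404 UMIs and 5344 genes per cell. The median share of mitochondrially encoded transcripts was 0.535% in CCR10pos cells and 1.41% in CCR10neg cells.

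The transcripts of the sort genes were examined to check the labels. CCR10 (ENSG00000184451, chromosome 17, 42678889 to 42683917 on GRCh38) was barely detected in either library. It gave 73 UMIs in CCR10pos cells, 0.589 CPM (counts scaled to the library total; exact Poisson interval 0.461 to 0.740), and 50 UMIs in CCR10neg cells, 0.443 CPM (0.329 to 0.584). The ratio of 1.33 had an interval of 0.914 to 1.94, so the full counts did not resolve a difference in CCR10 mRNA. A CCR10 UMI was found in 1.96% of CCR10pos cells and 1.295% of CCR10neg cells (exact binomial intervals 1.53 to 2.47% and 0.963 to 1.70%). In the clusters described below the share lay between 0.764% and 2.54%, and in the mesenchymal-like cluster, in which CCR10 was not expected, it was 2.5% (2 of 80 cells, 0.304 to 8.74%) at a median of 40020 UMIs per cell, too few cells to set a background. The secretory-like cluster had the highest share (2.54%, 1.68 to 3.67%) and level (1.204 CPM, 0.80 to 1.74) at a median of 20247.5 UMIs per cell, and cluster 2 the lowest (0.764%, 0.382 to 1.36%; 0.229 CPM, 0.114 to 0.41) at 32576 UMIs. After thinning to 12500 UMIs per cell, the ratio was 2.27 with an interval of 1.17 to 4.62, from 31 and 14 UMIs, and the shares were 0.880% and 0.400%. The thinned interval excludes 1, which that of the full counts does not. The thinned counts are 1 random draw, however, and the interval does not cover the draw. Thinning also left out shallower cells and weighted each cell alike. Whether CCR10 mRNA differed between the libraries is thus undecided. The gate was set on the protein, so these levels describe the mRNA only.

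EPCAM (ENSG00000119888, chromosome 2, 47345158 to 47387601 on GRCh38) was lower in CCR10pos cells, at 144 CPM (142 to 146) against 216 CPM (213 to 219), a ratio of 0.666 (0.654 to 0.679). Within the cluster led by cell cycle genes EPCAM stood at 265 CPM, above the other clusters, and EPCAM was also lower in CCR10pos within each of the 6 clusters with at least 100 cells of each library (log2 ratios of -0.449 to -0.193, and -0.276 with equal cluster weights, against -0.586 for whole libraries). An EPCAM UMI was found in 88.4% of CCR10pos and 92.6% of CCR10neg cells, and in 72.6% and 85.4% after thinning. In the mesenchymal-like cluster the share was 56.25% at 63.98 CPM. EPHA3, an ephrin receptor, gave 8 and 3 UMIs, a ratio of 2.43 with an interval of 0.582 to 14.2.

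The cells of both libraries were clustered together to ask which kinds of cell each gate held, and the makeup of the libraries differed widely. Secretory-like cells made up 22.4% of CCR10pos cells (exact binomial interval 21.0 to 23.8%) and 6.84% of CCR10neg cells (6.06 to 7.68%), a ratio of 3.27. These intervals do not cover where the cluster ends: under other clustering settings and cell filters the shares lay between 14.18% and 29.9% in CCR10pos and between 3.78% and 11.03% in CCR10neg, higher in CCR10pos each time. A cluster led by cell cycle genes held 10.9% of CCR10pos cells (9.88 to 11.9%) and 39.9% of CCR10neg cells (38.3 to 41.5%), 3.67 times the CCR10pos share. With the cycle lists left out of the genes used for clustering, such a cluster held 10.55% and 39.4%. A small mesenchymal-like cluster held 71 CCR10pos cells, 1.99% (1.55 to 2.499%), and 9 CCR10neg cells, 0.233% (0.107 to 0.442%). The 3 unnamed clusters without cycle genes also differed. Cluster 3 held 26.5% of CCR10pos and 10.4% of CCR10neg cells, cluster 2 held 12.8% and 25.4%, and cluster 5 held 15.6% and 11.0%. The shares of these unnamed clusters were not followed under other settings. At resolution 0.3 there were only 5 clusters in all, against 7.

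The secretory-like name rested on 12 markers at least 2-fold above other cells, among them SCGB1A1, the club cell secretory protein, and the mucins MUC5AC and MUC5B. The mesenchymal-like name rested on 12 markers such as the fibrillar collagens COL1A1 and COL3A1. The squamous-like cluster, with 10 markers including SPRR1B, a cornified envelope protein, held 9.87% of CCR10pos and 6.22% of CCR10neg cells. That order turned round under 3 other settings, 1 of the clustering and 2 of the cells kept, so no direction is read from it. Clusters 2, 3 and 5 met no marker set. Cluster 2 was led by ADAMTS1, the alarmin IL33, NET1, CCND2 and SOX7, cluster 3 by AMTN, IGFL1, APOE, CCK and MMP9, and cluster 5 by CCL3L3, NR4A3, CCL4L2, TSLP and IFNL3. Leading genes were BPIFA1, GSTA1, LYPD2, CEACAM5 and CLDN10 in the secretory-like cluster, HOXB7, HOXB5, HOXB4, NPPB and THY1 in the mesenchymal-like cluster, KRT16, SPRR1B, PPBP, RHCG and PI3 in the squamous-like cluster and MKI67, FAM111B, NCAPG, CLSPN and DEPDC1 in the cluster led by cycle genes. No cluster was named basal-like. The naming rule asks for markers 2-fold above other cells, which a class spread over most clusters can hardly meet. The missing name therefore does not show that basal cells were absent. In the secretory-like cluster 11 of 12 basal markers were at least 1.5-fold below other cells and 1 above (median log2 -2.81). In clusters 2 to 5 the basal medians lay between -0.046 and 0.353. The basal keratin KRT5 stood at 26.9 CPM in the secretory-like cluster and 180 CPM in the mesenchymal-like cluster, and between 273 and 565 CPM in clusters 2 to 6. With 1 library per group, a cluster mostly of 1 library may reflect that library. The cells were sorted on EpCAM and CCR10, so these shares do not describe the unsorted culture. The secretory-like cells had fewer UMIs, with a median of 20247.5.

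**Figure D1:**
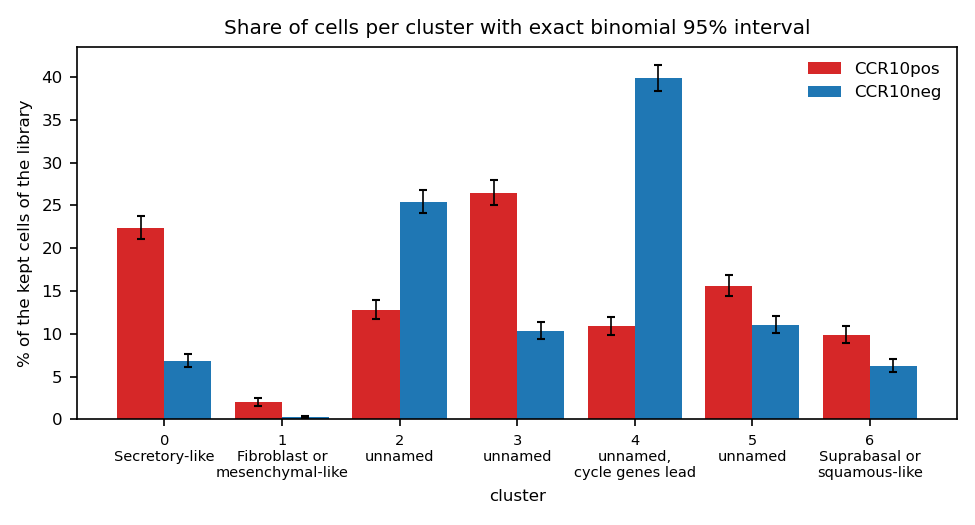
Share of kept cells (%) in each of the 7 clusters for CCR10pos (red) and CCR10neg (blue), with exact binomial 95% intervals as error bars. The secretory-like cluster holds 22.4% of CCR10pos and 6.84% of CCR10neg cells, and the cluster led by cycle genes 10.9% and 39.9%.

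Summed over the cells of each library, secretory and matrix genes were higher in CCR10pos. SCGB1A1 (ENSG00000149021, chromosome 11, 62405103 to 62423195 on GRCh38) stood at 368 CPM against 116 CPM, 3.17-fold higher (log2 ratio 1.67, counting interval 1.64 to 1.69). WFDC2, a secreted protease inhibitor, was at 2685 and 1125 CPM, 2.38-fold higher (log2 1.25, 1.25 to 1.26). The membrane mucin MUC1 was 2.45-fold higher, the mucosal chemokine CXCL17 2.70-fold and the adhesion molecule CEACAM6 3.26-fold. COL1A2 (ENSG00000164692, chromosome 7, 94394561 to 94431232 on GRCh38) and COL1A1, the chains of type I collagen, were 8.75-fold (log2 3.13, 3.02 to 3.25) and 4.33-fold higher (log2 2.12, 2.04 to 2.19). They stood at 1869 and 1934 CPM in the 71 CCR10pos cells of the mesenchymal-like cluster, against 52.7 and 65.0 CPM in the whole library. These cells also held the keratin KRT17 at 1020 CPM. With equal cluster weights, which leave that cluster out, the log2 ratios of COL1A2 and COL1A1 were 1.28 and 0.455. The whole-library ratios of these collagens therefore rest largely on that small cluster.

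Others among the 12 highest genes that passed the naming rule were MYEOV (log2 1.51), the histone genes HIST1H2AC (1.36) and HIST1H2BD (1.25), the actin-severing protein GSN (1.20) and the lipid carrier APOE (1.11). Histone genes have near-identical copies, so their values are uncertain. Of 5814 genes with at least 20 CPM, 31 were at least 2-fold higher, and 25 of these were also at least 2-fold above other cells in the secretory-like cluster. Of the 31 genes, 7 were at least 2-fold above other cells in the mesenchymal-like cluster.

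Proliferation genes were lower in CCR10pos. MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385 on GRCh38), the standard marker of dividing cells, stood at 13.6 against 53.2 CPM, 3.91-fold lower (log2 -1.97, -2.04 to -1.89). TOP2A, the topoisomerase of mitotic chromosomes, was 3.66-fold lower, HMGB2 3.52-fold and the mitotic kinase CDK1 3.42-fold. RRM2 and TYMS, enzymes of deoxynucleotide synthesis, were 3.20-fold (log2 -1.68, -1.72 to -1.64) and 2.83-fold lower. RAD51AP1, KIAA0101, UBE2C, SMC4, CENPK and ZWINT, with roles in DNA repair, replication and chromosome segregation, had log2 ratios of -1.80, -1.72, -1.68, -1.59, -1.57 and -1.39. In all, 88 genes were at least 2-fold lower, of which 86 were at least 2-fold above other cells in the cluster led by cycle genes.

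Counting intervals lay wholly beyond 2-fold for 110 of these higher and lower genes. The authors' normalized values weight each cell alike and also set the libraries apart by a log2 shift of 0.21. With them the counts were 96 higher and 63 lower, so that higher genes made up 60.4% in place of 26.1%, and with equal weight per cell alone they were 52 and 96 (35.1% higher). Leaving out the cluster led by cycle genes left 10 higher and 6 lower genes.

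**Figure D2:**
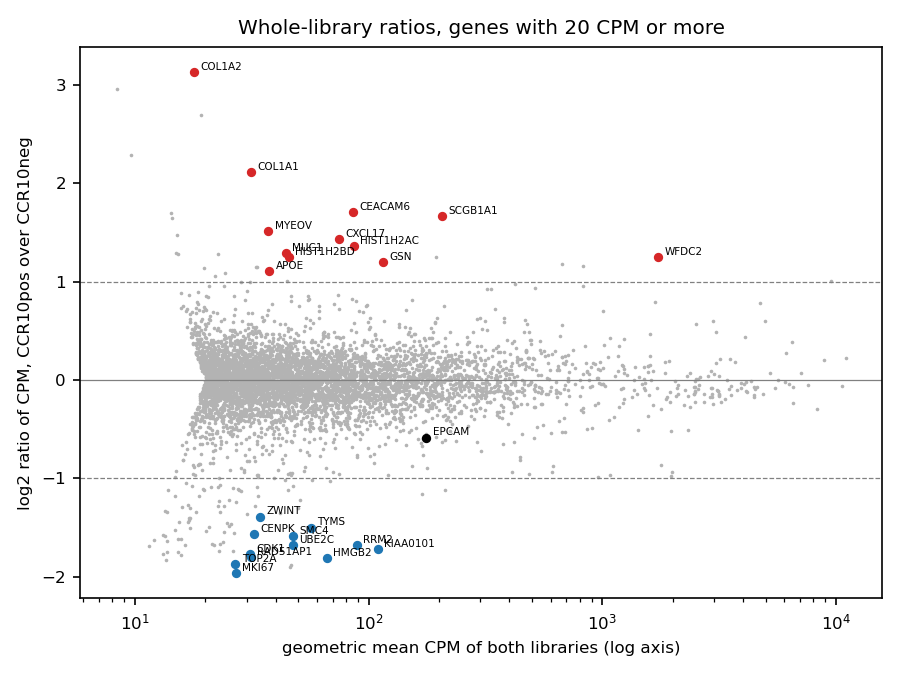
Log2 ratio of whole-library CPM (CCR10pos over CCR10neg) against geometric mean CPM on a log axis, for genes with at least 20 CPM in either library. Each grey point is a gene, red and blue points are the 12 highest and 12 lowest named genes, the black point is EPCAM, and dashed lines mark 2-fold. COL1A2 lies highest among the named genes at 3.13 and MKI67 lowest at -1.97.

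Gene lists fixed before the data were examined were ranked against 10000 random lists matched for size and expression, as a description of these libraries. Of 29 lists with at least 5 measured members, 11 lay above and 5 below the middle 95% of random lists. The 10 measured secretory markers were all higher in CCR10pos, 8 of them at least 2-fold (median log2 1.36, interval 1.28 to 1.49, percentile 100). Without the secretory-like cluster, or with members of at least 20 CPM, this list was not counted as above random lists. Lists with fewer than 5 members are not ranked. SLPI, an antiprotease, was at 1234 and 554 CPM, and AGR2 at 113 and 64.0 CPM. The 6 fibroblast and mesenchymal markers had a median of 2.85 (percentile 100), with POSTN at 16.3 and 1.77 CPM and COL3A1 at 17.9 and 1.95 CPM. Among 26 mesenchymal transition and matrix genes, 20 were higher (median 0.30, percentile 100), among them SPARC (log2 2.69), MMP9 (1.501) and CTGF (1.47). Without the mesenchymal-like cluster the matrix list had a median of 0.034 and did not stand apart (percentile 69.39), but it lay above random lists with equal cluster weights, which also leave that cluster out (0.044, 98.96), and without the mesenchymal-like, secretory-like and cycling clusters together (0.187, 100). The fibroblast list then kept 3 members with at least 5 CPM, too few to be ranked, with a median of 0.66.

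Genes of the aberrant basaloid cells of fibrotic lung were higher for 18 of 20 members (median 0.42, percentile 100). The keratin KRT17 was among the 2 lower members, and within the secretory-like cluster it was at 1127 and 1542 CPM. GDF15, a stress-induced cytokine, was at 443 and 233 CPM, fibronectin FN1 at 459 and 242 CPM and MMP7 at 74.1 and 41.1 CPM. Of 20 senescence and p53 target genes 17 were higher (median 0.25, percentile 100), with the cell cycle inhibitor CDKN2A at 96.0 and 58.2 CPM. Some lists share members, so their percentiles are not independent. GDF15 and CDKN2A are on both the basaloid and senescence lists, and FN1 is on the basaloid and matrix lists. SLPI is on both the secretory and antimicrobial lists. All 14 antimicrobial and acute phase genes were higher (median 0.57, percentile 100), including DEFB1 (log2 1.36) and the acute phase proteins SAA2 (0.98) and SAA1 (0.79), near-identical genes whose reads may be split uncertainly. With equal cluster weights the basaloid, senescence and antimicrobial medians were smaller, at 0.132, 0.103 and 0.135, and still stood apart. Smaller shifts were seen for the chemokine and cytokine list (median 0.15, percentile 99.73), in which IL6 was at 203 and 115 CPM while TSLP was lower, at 12.9 and 25.2 CPM. Antigen presentation (0.20, percentile 98.93) and the immediate early and dissociation response (0.20, 99.93) also lay above random lists. Antigen presentation did not stand apart without the secretory-like cluster (0.14, percentile 96.52) or with members of at least 20 CPM (0.14, 95.52), and the immediate early list did not with equal cluster weights (0.019, 92.93). Above random lists were also keratins of simple epithelium and junctions (0.18, 99.41), and suprabasal and squamous genes (0.34, 99.81), of which KRT6A was lower, at 349 against 679 CPM. With equal cluster weights in both libraries the suprabasal median was -0.14 and the chemokine median -0.006, and with members of at least 20 CPM the simple keratin median was -0.067, so no direction is read from these 3 lists.

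The 40 S phase genes and the 49 G2 and M phase genes were all lower in CCR10pos, with medians of -1.32 and -1.62 (both percentile 0). CLSPN, a replication checkpoint protein, was at 24.2 and 89.0 CPM, and CENPE, a mitotic motor, at 4.84 and 19.2 CPM. Basal markers were modestly lower (9 of 12 members, median -0.23, percentile 0.26), with KRT5 at 300.1 and 470 CPM and KRT14 at 18.8 and 40.9 CPM, and did not stand apart with equal cluster weights (-0.058, percentile 10.56). The 12 mitochondrially encoded genes were all lower (median -0.90, percentile 0), and made up 0.864% of CCR10pos and 1.55% of CCR10neg UMIs. With equal cluster weights their median was -0.318. Cytosolic ribosomal protein genes had a median of -0.098 (percentile 0.29), which was 0.01 with equal cluster weights.

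Lists within the middle range of random lists were the interferon response (median 0.071, percentile 94.36), nuclear oxidative phosphorylation (0.076, 93.08), Notch (0.10, 89.5), YAP and actin targets (0.059, 85.15) and cholesterol synthesis (0.079, 80.96). EGF receptor ligands and MAPK feedback (0.038, 75.86), Wnt (0.057, 70.11), Eph receptors and ephrins (0.006, 49.91), hemidesmosome and desmosome (-0.014, 49.54) and oxidant response (-0.037, 30.51) lay there too. So did glycolysis and hypoxia (-0.098, 6.98), the unfolded protein and integrated stress response (-0.10, 6.13) and alveolar type 1 markers (-0.23, 3.56). With equal cluster weights the oxidant response lay below random lists (-0.13, percentile 0) and Notch above them (0.078, 99.35). The Wnt inhibitor DKK1 was 2.84-fold lower in CCR10pos, although its list did not stand apart. For 6 lists of other cell types fewer than 5 members were measured. Their values in CCR10pos and CCR10neg were 33.2 and 25.4 CPM for TUBA1A (ciliated), 24.2 and 13.9 for SLC34A2 and 73.0 and 67.7 for LAMP3 (alveolar type 2). EGFL7 (endothelial) was at 29.2 and 29.02 CPM, CD68 (myeloid) at 16.2 and 17.6, IL7R (T and NK cell) at 77.9 and 87.6 and SDC1 (B and plasma cell) at 286 and 248.

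**Figure D3:**
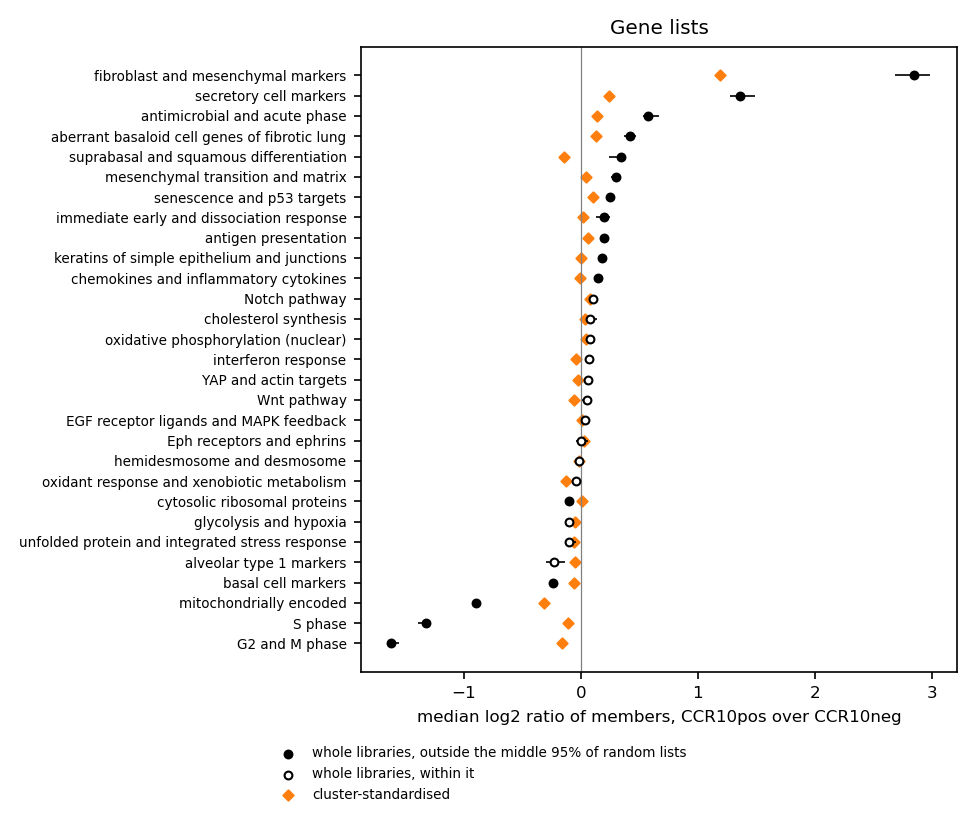
Median log2 ratio (CCR10pos over CCR10neg) of the members of 29 gene lists. Circles are whole libraries (filled outside the middle 95% of random lists) with bars for the 95% range under Poisson resampling of counts, and diamonds are means given the same cluster weights in both libraries. The S phase median is -1.32 for whole libraries and -0.10 with equal cluster weights.

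The share of cells expressing cycle genes was then compared after thinning every cell to 12500 UMIs. The planned threshold of 2 UMIs over a list was reached by nearly every cell: 90.6% of CCR10pos and 96.6% of CCR10neg cells for the S phase list, and 99.6% and 99.9% for the G2 and M phase list. This measure is saturated. At least 20 UMIs, a threshold chosen after this was seen, were found for the S phase list in 11.2% of CCR10pos cells (exact binomial interval 10.1 to 12.3%) and 39.4% of CCR10neg cells (37.8 to 41.0%). For the G2 and M phase list the shares were 13.3% (12.1 to 14.4%) and 45.1% (43.4 to 46.7%). Without thinning the S phase shares at 20 UMIs were 21.3% and 47.9%, and the G2 and M phase shares 62.9% and 74.5%. The summed lists stood at 692 against 1598 CPM for S phase and 1117 against 2191 CPM for G2 and M phase. Free RNA from dividing cells may also add UMIs to such lists, which was not tested, and these are list levels, not phase calls. Thinning left out 165 CCR10pos and 365 CCR10neg cells.

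Most of the whole-library differences were small with the clusters weighted alike. With equal cluster weights in both libraries, 1 gene with at least 20 CPM on that scale was at least 2-fold higher, PSCA, a surface antigen. At least 2-fold lower were 3 genes, TSLP, C1orf56 and LRRC75A. Of the genes 2-fold apart in whole libraries, 3 of the 31 higher and 2 of the 88 lower kept that size, whatever their CPM. Of the gene lists, 6 of the 11 above and 3 of the 5 below random lists still stood apart. MKI67 had a log2 ratio of -0.29 and RRM2 of -0.079 in this comparison, SCGB1A1 of 0.26 and WFDC2 of 0.21. COL1A2 fell from 3.13 to 1.28, at levels of 1.21 to 7.78 CPM within the clusters compared. Cycle gene values here rest mostly on the cluster led by cycle genes, where MKI67 stood at 116 CPM (1.62 CPM in other cells). In that cluster the ratios were -0.236 for MKI67 and -0.023 for RRM2. Within the secretory-like cluster and clusters 2, 3, 5 and 6 they were larger, at -2.59 to -1.52 for MKI67 and -1.23 to -0.525 for RRM2. The S phase median was -0.10, the secretory median 0.24 and the fibroblast median 1.19 over the 6 members of the whole libraries, of which 3 had at least 5 CPM on that scale (median 0.455, not ranked). These 4 genes of equal weighting were named after their values were seen.

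Within the 6 clusters with at least 100 cells of each library, 1 to 7 genes were at least 2-fold higher and 2 to 8 lower. In the secretory-like cluster PSCA (log2 1.61, 1.43 to 1.80), TFF3, a mucus-associated trefoil peptide (1.67, 1.33 to 2.02), LYPD2 (1.28) and S100A7 (1.03) were higher in CCR10pos, whereas SCGB1A1 was nearly level at 2199 and 1990 CPM. In each of clusters 2 to 6 SCGB1A1 was at least 2-fold higher in CCR10pos, by log2 ratios of 1.03 to 1.81, at levels of 31.2 CPM in cluster 2 to 237 CPM in cluster 6 of that library. C1orf56 was at least 2-fold lower in the same clusters (log2 -1.36 in cluster 4 and -1.03 in cluster 5). In cluster 2, CCK and the gelatinase MMP9, which lead cluster 3, were higher (log2 2.08 and 2.53) and the serpins SERPINB4 and SERPINB3, close paralogs whose reads may be split uncertainly, were lower (-1.57 and -1.34). In cluster 6 the cytokines CSF2 (1.05) and CCL2 (1.11) were higher. The genes in this paragraph were chosen after their values were seen.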

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

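Leaving out single clusters and the threshold of 20 UMIs were chosen after the results were seen; the other alternatives were planned. Median-of-ratios and TMM scaling gave 29 genes higher and 104 lower each, against 31 and 88. No cell filter, the stricter filter and leaving out Scrublet calls changed at most 10 of 7436 cells, so their unchanged counts show nothing. The number of higher genes moved to 51 with thinned cells, 52 with equal weight per cell and 96 with the authors' normalized values. Higher and lower counts were 1 and 3 with equal cluster weights, 108 and 240 at 5 CPM, 1862 and 1068 with no minimum, 126 and 226 at fold 1.5 and 9 and 29 at fold 3, where the construction of the setting changes the count. They were 10 and 6 without the cycling cluster, and 4 and 5 without it, the secretory-like and the mesenchymal-like clusters; without the secretory-like cluster 13 were higher. The 12 highest and 12 lowest named genes kept their direction in every alternative run for them. They were chosen for large ratios with the same sign in each of the 6 clusters, which largely fixed this beforehand.

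Lists above random lists numbered 7 with equal cluster weights, 7 at 20 CPM for members and 5 without the 3 clusters, against 11. Not every drop is a fall into the middle range. With equal cluster weights and at 20 CPM the fibroblast list had fewer than 5 members and could not be ranked. The suprabasal median changed sign with equal cluster weights (-0.14), without the cycling cluster (-0.055) and without the 3 clusters (-0.29). With equal cluster weights the chemokine median was -0.006 and the ribosomal median 0.01, and at 20 CPM the simple keratin median was -0.067. Some lists within the middle range came to stand apart. The oxidant response lay below random lists with equal cluster weights (-0.13), without the secretory-like cluster (-0.178) and without the 3 clusters (-0.183). Notch lay above with equal cluster weights (0.078) and without the cycling cluster (0.142), where oxidative phosphorylation (0.078) lay above and glycolysis (-0.102) and Wnt (-0.162) below. Without the secretory-like cluster YAP targets lay above (0.162), and with equal weight per cell alveolar type 1 markers (-0.327) and glycolysis (-0.155) lay below. Without the mesenchymal-like cluster the fibroblast list had 3 members left and was not ranked. The list medians with the cells lacking cycle transcripts were not run, because 0 of 7436 cells lacked them.

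The log2 ratio of CCR10 was 1.18 after thinning, from 31 and 14 UMIs in 1 random draw, too few to fix its size. The secretory-like log2 share ratio was 1.44 at resolution 0.3, against 1.71, and lay within its interval elsewhere, while the shares themselves moved from 22.4% and 6.84% to 14.18% and 3.78% with no cell filter, 29.9% and 11.03% at resolution 0.3 and 28.75% and 10.09% without Scrublet calls. The squamous-like ratio was 0.67 and became 0.30 at resolution 1.0, 0.26 with 1000 variable genes, -0.93 without the cycle lists, -0.09 with the stricter filter and -1.0 without Scrublet calls; at resolution 0.3 no cluster met its markers. The cycling and mesenchymal-like ratios stayed within their intervals in every setting tried. The S phase share ratio (log2) was -0.018 at 1 UMI, -0.57 at 5, -1.82 at 20 and 0.001 without thinning, against -0.092. The G2 and M phase ratio was -0.11 at 5 UMIs and -1.77 at 20. The median number of lower genes within clusters was 8 at resolution 0.3, against 4.5. The cause of the changes not ascribed to a setting above was not tested. No paired analysis was possible because each group has 1 library.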

Other observations

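The tests on the mesenchymal-like cluster and on secretory transcripts outside the secretory-like cluster were chosen after the results were seen, and those on 3 uniformly lower genes before. The tests on secretory transcripts were also redefined after a result was seen. Run at first over clusters 2 to 6, with 4 genes, they gave a median log2 ratio of 1.34 against 1.69 for whole libraries, which counted for free RNA, and 30.3% of UMIs in the top 1% of cells, which decided nothing. Cluster 6 was then set apart because its CCR10pos cells held 237 CPM of SCGB1A1, and all other values come from that later definition. The share of UMIs in the top 1% of cells (9.7% in clusters 2 to 5) was then replaced too, because S100P and AGR2 supplied 69.3% of those UMIs.

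Cluster 5 carried an inflammatory profile in both libraries. Of 26 chemokine and cytokine genes, 19 were at least 1.5-fold above other cells (median log2 0.84), with 18 in each library taken alone (medians 0.85 in CCR10pos and 0.82 in CCR10neg). The immediate early and dissociation response was raised there as well, with 7 of 17 genes at least 1.5-fold higher and 1 lower (median 0.44), so a response to handling is not excluded. In cluster 5 the leading genes included IL17C (396 against 49.3 CPM in other cells) and the interferon lambda genes IFNL2 (96.2 against 9.64 CPM) and IFNL3 (69.5 against 6.79 CPM), which are close paralogs. TSLP, an epithelial alarmin, differed between the libraries within this cluster, at 49.1 CPM in CCR10pos and 147 CPM in CCR10neg (log2 -1.58, counting interval -1.69 to -1.47). It was also lower within cluster 3 (-1.92, -2.21 to -1.64) and higher within cluster 6 (0.82, 0.28 to 1.39). CCL4L2, a member of a gene family with near-identical copies, was at 11.0 and 40.8 CPM in cluster 5, while CCL3L3 was level at 32.7 and 32.8 CPM.

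Cells of the mesenchymal-like cluster carried both collagen and keratin transcripts, although the gate required EpCAM. In its CCR10pos cells COL1A1 stood at 1934 CPM and LUM at 50.5 CPM beside KRT17 at 1020 CPM and KRT5 at 184 CPM, and all 71 cells had at least 5 UMIs of basal and 5 of mesenchymal markers. That count shows little for the basal markers. The basal marker S100A2 stood at 7484 CPM in the whole CCR10pos library, so free RNA alone could bring cells of this depth over 5 UMIs. Doublets of a mesenchymal and an epithelial cell may contribute: the 35 cells richer in basal markers had 1.88 times the median UMI total of the other 36 (57179 against 30434), and fewer mesenchymal markers (24.6 against 76.0 per 10000 UMIs). Free RNA in the proportions of the library is argued against as the whole cause, as basal markers in the cluster reached 33.8% of the library level (26.9 to 41.0% over resampled cells), while SCGB1A1 in clusters 2 to 5 allowed a fraction of up to 9.57%; with cluster 6 included, as first done, it was 16.4% and had left this open. It remains open for the 36 poorer cells, at 9.7%. Cells that truly co-express both programmes were not tested, nor was a real difference between the sorted populations.

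SCGB1A1 was higher in CCR10pos outside the secretory-like cluster, at 31.2, 32.8 and 32.2 CPM in clusters 2, 3 and 5 against 15.2, 11.7 and 14.6 CPM in CCR10neg. In cluster 4 it stood higher in both libraries, at 49.6 CPM in CCR10pos and 24.25 CPM in CCR10neg. In clusters 2 to 5, 67.2% of CCR10pos against 26.5% of CCR10neg cells had a UMI of it (median depths 36526 and 29261 UMIs). A few misplaced secretory cells or doublets, up to 1% of cells (24 of 2351 in CCR10pos), are argued against in clusters 2 to 5. Without the top 1% of cells of each library, the median log2 ratio of 9 genes largely restricted to secretory-like cells was 1.06 there, against 0.88 with them. That of SCGB1A1 was 1.35 (1.25 to 1.45). The earlier definition did not give this exclusion, and a larger share of such cells was not tested. Free RNA from the larger secretory population could produce the like levels in clusters 2, 3 and 5, though cluster 4 stood higher. The median of 0.88 stood against 1.51 for whole libraries, with AGR2 at -0.15 and PSCA at 1.78. The later test thus leaves free RNA open where the earlier definition favoured it. In cluster 6 of CCR10pos the SCGB1A1 level, by which that cluster was set apart, was 6.73 times (6.40 to 7.08) that of clusters 2 to 5. The 9 genes were 3.32 to 16.2 times as high there (3.52 to 24.5 times in CCR10neg). They were chosen for low levels in clusters 2 to 5 with cluster 6 left out, and only 4 genes passed with it included. Part of their excess in cluster 6 may come from this choice. Free RNA shared alike by all cells would not give the SCGB1A1 level of cluster 6. Misplaced secretory cells were not tested there. Low expression that differs between the sorted populations was not tested.

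C1orf56, LRRC75A and CTNNB1 were the 3 genes with at least 20 CPM that were lower in CCR10pos by at least 0.5 on the log2 scale within each of the 6 clusters, with medians of -1.07, -1.07 and -0.70. The median over these genes was -1.32 after thinning. This cannot decide on sequencing depth per cell, because thinning keeps the expected proportions within a cell and CPM are already scaled to total UMIs. Less nuclear RNA in the CCR10pos library remains open, with a median of -0.09 over 8 nuclear or intron-retaining RNAs such as MALAT1 (-0.36) and NEAT1 (0.04). C1orf56 (chromosome 1, 151047740 to 151051986 on GRCh38) overlaps CDC42SE1 (151050971 to 151070325) on the opposite strand. CDC42SE1 was lower as well, by log2 ratios of -0.66 in cluster 3 and -0.48 in cluster 6. Whether reads of this pair were mixed was not tested. A biological difference between the sorted populations stays open and was not tested.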
